A study of Homo sapiens with 22 samples.

How the data were processed

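RNA was sequenced from 14 xenograft tumours of SUM149PT cells, per the labels with stranded mRNA libraries made from 500 ng of total RNA. Each tumour was assigned to its group by its treatment label. Per the submitters' processing notes, STAR 2.5.1b, edgeR (no version) and the builds hg19 and mm10 were used, with no role given for each. How reads of the mouse host were treated is not given in the sources used here. The authors deposited log2 values, read here as log2(CPM + 1) over a scaled library size, since every CPM obtained this way was a whole multiple of 1 step per tumour. Whole reads, within 0.05 of a read, were recovered for 100% of the values. A further deposited table holds 14 columns of per-sample values whose names match titles of both cultured cells and tumours, and it was not used. The comparisons planned for the 8 libraries of cultured cells given A196 and tunicamycin (5 contrasts) were not analysed here.

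Between 5152957 and 7465406 reads per tumour were recovered, so genes near 1 CPM rest on few reads. The table listed 17432 genes. Of its symbols 27 read as dates and 4 were repeats, and none of these is named. Genes with at least 1 CPM in at least 3 tumours were tested (13580 genes).

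Log2 values of all 14 tumours were fitted in R 4.3.3 with limma 3.58.1, with 1 mean per group, no covariate, empirical Bayes moderation with an intensity trend and 10 residual degrees of freedom. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The design had allowed for log2 values as deposited. The 6 contrasts were each compound and the combination against vehicle, the combination against each compound, and the interaction. Of 36 gene lists fixed in advance, those with at least 5 tested members (34) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera was repeated with an estimated correlation, and fry was run. List members were also adjusted over the list alone.

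Genes were named by a rule. It took the 8 largest rises and 8 largest falls among genes past the test whose groups did not overlap and whose mean log2 value was at least 1, skipping clone, LOC, open reading frame, antisense and pseudogene symbols. It added up to 4 members with the smallest p of each list that passed or held at least 3 genes past the test, and a fixed set of H4K20, unfolded protein response, heat shock, keratin and lineage genes. Some genes the rule took are not reported here. Where no gene passed, 3 genes per direction with the smallest p were given as values. The groups, contrasts, tests, lists, naming rule and most alternatives were fixed before the data were examined.

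The test was tried on data simulated from these tumours' means and spreads averaged over genes of similar level. Of 2-fold changes it recovered 76.1% for A196, 64.2% for 17AAG and 73.1% for the combination against vehicle. Against 17AAG and A196 the combination had 67.2% and 62.7%. For 1.5-fold it was 14.9% to 26.9%, with 113 to 127 calls. With 1 list of independent genes shifted, camera called it alone of 34, leaving the preset correlation untested.

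Alternatives fixed in advance were no filter on low genes, at least 5 CPM, pseudocounts of 0.25 and 5, upper quartile and quantile scaling, no intensity trend, array weights, only the groups compared in the fit, the tumour number as a block, and each tumour left out in turn. Alternatives chosen after the data were seen were voom on the recovered reads, the mitochondrial share as a covariate, leaving out the 3 tumours over 40% mitochondrial reads, and removal of a GC and length trend. GC content and length came from GENCODE transcripts matched by symbol for 94.2% of tested genes, 99.5% of ZNF genes and 96.3% of cytokine genes. Calls were compared with those of other splits of the tumours, at most 100 per contrast.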

Results

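RNA-seq was measured in 14 orthotopic xenograft tumours of SUM149PT, an established human line of inflammatory, basal-like breast cancer, grown in immunodeficient NSG mice. The tumours fell into 4 groups. Mice received vehicle (4 tumours), A196 at 25 mg/kg daily (4 tumours), 17AAG at 12.5 mg/kg on 5 days per week (3 tumours) or both compounds (the combination, 3 tumours). A196 inhibits SUV420H1 and SUV420H2 (KMT5B and KMT5C), the enzymes that place the di- and trimethyl marks on lysine 20 of histone H4. 17AAG (tanespimycin) inhibits the chaperone HSP90. The values were log2(CPM + 1) for 17432 genes, of which 13580 reached 1 CPM in at least 3 tumours and were tested. Per tumour, 5152957 to 7465406 reads were recovered. Mitochondrially encoded genes took 31.6 ± 11.6% of the reads in vehicle tumours (SD, n = 4) and 32.5 ± 11.2% with A196 (SD, n = 4). The share was 25.0 ± 18.9% with 17AAG (SD, n = 3) and 24.7 ± 4.65% with the combination (SD, n = 3). Vehicle tumour 2, A196 tumour 3 and 17AAG tumour 1 exceeded 40%. All tumour pairs within a group differed by more than sampling noise, with a chi-square per degree of freedom of 4.75 to 13.7. The labels do not tie tumours to mice, so gene p-values measure only the spread between these tumours, which may in part be technical. Values after ± are standard errors of log2 fold changes unless named as SD. Adjusted p is from limma (Benjamini-Hochberg) for genes and camera for lists. At the preset correlation camera compares genes, taken as nearly independent, not tumours. Within the list alone means adjusted over its members only. A list's second median is without the tumours that moved it over 1.5 times, and its p is from all tumours. The 14 other fits of a list are the alternatives besides leaving 1 tumour out, the estimated correlation and fry. Fold changes are on the log2(CPM + 1) scale and understate the change of genes with low CPM.

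**Figure D1:**
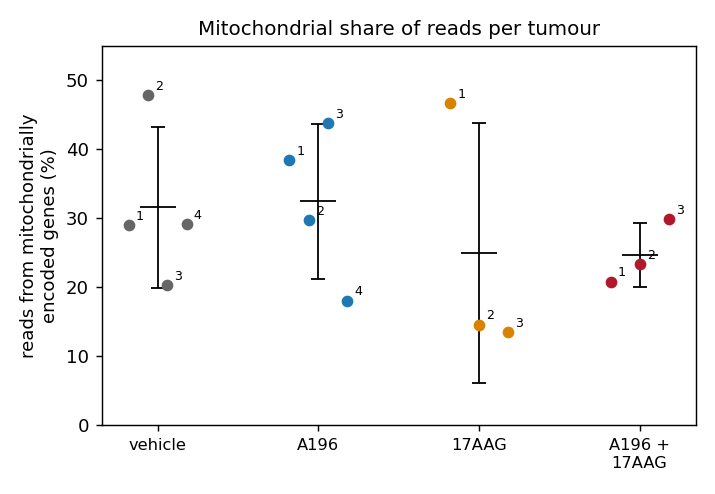
Percent of reads from mitochondrially encoded genes (vertical axis) in each tumour of the 4 groups, with the tumour number beside each point and the mean ± SD as bars. Vehicle tumour 2 at 47.9%, A196 tumour 3 at 43.8% and 17AAG tumour 1 at 46.7% lie above 40%.

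The comparison of A196 with vehicle asked what inhibition of the H4K20 methyltransferases alone did to the tumours. S100A9, a calcium-binding subunit of calprotectin, rose from 237 ± 56.0 CPM in vehicle tumours (SD, n = 4) to 530.0 ± 65.3 CPM with A196 (SD, n = 4). Its log2 fold change was 1.18 ± 0.16 (adjusted p = 0.00607), and it was the only gene of 13580 past the test. The NF-kB and inflammatory cytokine list rose, with 26 of its 27 members higher (median 0.52, camera adjusted p = 3.70e-10, adjusted p = 0.156 with an estimated correlation). No member passed over all genes, and 9 did, all higher, within the list alone. Members with the smallest p were SOD2, the mitochondrial superoxide dismutase (1.00 ± 0.25, adjusted p = 0.289), and the acute-phase protein SAA1 (1.28 ± 0.34, adjusted p = 0.289). Next were the NF-kB subunit RELB (0.68 ± 0.19, adjusted p = 0.289) and the neutrophil chemokine IL8, now CXCL8 (1.31 ± 0.40, adjusted p = 0.289).

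Interferon and antigen presentation genes were also higher with A196 as lists. The type I interferon list rose (median 0.39, or 0.23 without A196 tumour 1, camera adjusted p = 1.12e-06, adjusted p = 0.161 with an estimated correlation). Over all genes, or within the list alone, 0 of its 27 members passed. Examples are IFIT2 (1.31 ± 0.46, adjusted p = 0.324) and IFI6 (1.02 ± 0.39, adjusted p = 0.343). The antigen presentation list rose (median 0.22, or 0.12 without vehicle tumour 2 or A196 tumour 2, camera adjusted p = 7.26e-04, adjusted p = 0.305 with an estimated correlation). No member of its 22 passed over all genes or within the list alone. HLA-C was at 0.45 ± 0.14 (adjusted p = 0.295) and PSMB8, an immunoproteasome subunit, at 0.38 ± 0.13 (adjusted p = 0.324). The NRF2 target list (median 0.24, or 0.16 without vehicle tumour 4, camera adjusted p = 0.00148), the hypoxia and glycolysis list (median 0.18, or 0.09 to 0.27 without vehicle tumour 1, 3 or 4 or A196 tumour 3, camera adjusted p = 5.33e-04), and the lists of N-glycosylation enzymes (median 0.14, camera adjusted p = 0.00253), autophagy and lysosome (median 0.14, camera adjusted p = 0.00134) and oxidative phosphorylation genes (median 0.07, or 0.04 without A196 tumour 4, camera adjusted p = 0.00148) rose. They had adjusted p between 0.156 and 0.494 with an estimated correlation. In these 5 lists 0 members passed over all genes, and 0, 2, 1, 0 and 4 members, all higher, did within the list alone. The 420 genes named ZNF, mostly zinc finger factors, fell as a list (median -0.09, camera adjusted p = 0.00478, adjusted p = 0.161 with an estimated correlation). None of them passed over all genes or within the list alone, and ZNF638 was at -0.43 ± 0.11 (adjusted p = 0.289). The ZNF call was lost without the 3 tumours over 40% mitochondrial reads (adjusted p = 0.0700).

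Further list calls with A196 rested on single tumours. The luminal epithelial list rose (median 0.17, or 0.08 to 0.10 without vehicle tumour 1 or 4 or A196 tumour 1, camera adjusted p = 0.0246, adjusted p = 0.156 with an estimated correlation), a call lost without vehicle tumour 1 or 4 (adjusted p up to 0.0975) and in 2 other fits. Ribosomal protein genes rose as a list (median 0.10, or 0.01 to 0.18 without vehicle tumour 3 or 4 or A196 tumour 1 or 3, camera adjusted p = 0.00134, adjusted p = 0.744 with an estimated correlation), a call lost without vehicle tumour 1 or 4 or A196 tumour 3 (adjusted p up to 0.487) and in 1 other fit. Canonical histone genes rose as a list (median 0.25, camera adjusted p = 0.0285, adjusted p = 0.494 with an estimated correlation), a call lost without vehicle tumour 2 or A196 tumour 1 or 4 (adjusted p up to 0.119) and in 3 other fits. The 5 tested macrophage and leukocyte markers rose as a list (median 0.42, or 0.24 to 0.27 without vehicle tumour 4 or A196 tumour 3, camera adjusted p = 0.0246, adjusted p = 0.156 with an estimated correlation), a call lost without vehicle tumour 1 or A196 tumour 1 or 4 (adjusted p up to 0.0676) and in 1 other fit. In these 4 lists 0 members passed over all genes, and 1, 1, 0 and 2, all higher, did within the list alone. The leukocyte pair was CD14 (0.83 ± 0.26, adjusted p = 0.295) and CD68 (0.47 ± 0.17, adjusted p = 0.334).

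The enzymes that A196 inhibits did not pass, with SUV420H2 at -0.36 ± 0.18 (adjusted p = 0.451) and SUV420H1 at 0.05 ± 0.11 (adjusted p = 0.891). SETD8, the H4K20 monomethyltransferase, was at -0.04 ± 0.12 (adjusted p = 0.926). The ER chaperone HSPA5 was at 0.22 ± 0.12 and the luminal transcription factor GATA3 at -0.10 ± 0.19 (adjusted p = 0.882), neither past the test. At an unadjusted p under 0.05 there were 1544 genes, 851 higher and 693 lower, and voom on the recovered reads called 1 gene. S100A9 lost its call without vehicle tumour 1 or 4 or A196 tumour 2 (adjusted p up to 0.0618). With limma 0 genes passed when low genes were kept or when the intensity trend was left out, and 2 passed with array weights or with only these groups in the fit. In simulated data for this comparison the test recovered 76.1% of 2-fold and 22.4% of 1.5-fold changes.

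The comparison of 17AAG with vehicle measured the response to HSP90 inhibition. KRT6C, a keratin of activated epithelium, rose from 36.0 ± 5.97 to 78.7 ± 8.77 CPM (SD, n = 4 and n = 3), or by 1.12 ± 0.19 (adjusted p = 0.0313). KRT17 rose by 0.78 ± 0.17 (adjusted p = 0.0341) and TRIM29, found in basal epithelium, by 0.63 ± 0.13 (adjusted p = 0.0319). KRT5 (0.27 ± 0.21, adjusted p = 0.550) and KRT14 (0.19 ± 0.15, adjusted p = 0.557), keratins of basal epithelium, did not pass. S100A9 rose by 0.94 ± 0.18 (adjusted p = 0.0313). EPAS1, the hypoxia-inducible factor HIF-2 alpha, rose by 0.92 ± 0.17 (adjusted p = 0.0313) and the glycolytic enzyme PGAM1 by 0.59 ± 0.12 (adjusted p = 0.0318). Other rises were those of the protocadherin PCDHGC3 (1.33 ± 0.28), the ribosome rescue factor PELO (0.99 ± 0.19) and MICAL2 (0.92 ± 0.22). GOLGA6L4 fell from 8.21 ± 2.60 to 2.56 ± 0.679 CPM (SD, n = 4 and n = 3, adjusted p = 0.0318). Other large falls were the semaphorin SEMA6C (-1.27 ± 0.25) and the proton pump subunit ATP6V1B1 (-1.10 ± 0.25), with adjusted p = 0.0313 and 0.0419. KRT6C, GOLGA6L4 and PCDHGC3 belong to families of near-identical sequence, so their values are uncertain.

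In all 132 genes passed with 17AAG, 33 higher and 99 lower. The basal epithelial list rose (median 0.31, camera adjusted p = 8.00e-07, adjusted p = 0.377 with an estimated correlation). Of its 26 members, 2 rose, 0 fell and 24 did not pass, against 7 higher and 0 lower within the list alone. The cholesterol synthesis list rose (median 0.31, or 0.20 without vehicle tumour 3, camera adjusted p = 1.87e-05, adjusted p = 0.537 with an estimated correlation). Over all genes, or within the list alone, 0 of its 25 members passed. SREBF2, the transcription factor that drives this pathway, was at 0.35 ± 0.11 (adjusted p = 0.0984). The ATF6 target and ER chaperone list rose (median 0.23, camera adjusted p = 0.00280, adjusted p = 0.537 with an estimated correlation). No member of its 24 passed over all genes or within the list alone. PDIA6, a protein disulfide isomerase, was at 0.38 ± 0.13 (adjusted p = 0.131). The ZNF list fell (median -0.13, camera adjusted p = 0.00280, adjusted p = 0.377 with an estimated correlation). Over all genes 1 of its 420 members rose, 8 fell and 411 did not pass, and within the list alone 1 was higher and 10 lower. ZNF638 fell by 0.67 ± 0.12 and ZNF84 fell by 0.83 ± 0.17. The HSP90 client list rose (median 0.21, or 0.13 without 17AAG tumour 2, camera adjusted p = 0.00728, adjusted p = 0.377 with an estimated correlation). Of its 20 members, 0 passed over all genes or within the list alone. The receptor EGFR was at 0.32 ± 0.13 (adjusted p = 0.221). The client call was lost without 17AAG tumour 2 (adjusted p = 0.0745).

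Stress and metabolic lists rose with 17AAG on calls that single tumours decided. The NRF2 target list rose (median 0.21, camera adjusted p = 0.0177, adjusted p = 0.377 with an estimated correlation), a call lost without vehicle tumour 4 or 17AAG tumour 3 (adjusted p up to 0.0671). The autophagy and lysosome list rose (median 0.13, camera adjusted p = 0.0273, adjusted p = 0.377 with an estimated correlation), a call lost without vehicle tumour 4 (adjusted p = 0.0671) and in 2 other fits. The hypoxia and glycolysis list rose (median 0.17, or 0.05 to 0.27 without vehicle tumour 1, 3 or 4 or 17AAG tumour 1 or 2, camera adjusted p = 0.0406, adjusted p = 0.686 with an estimated correlation), a call lost without vehicle tumour 1 or 4 or 17AAG tumour 1 or 3 (adjusted p up to 0.529) and in 5 other fits. N-glycosylation enzymes rose as a list (median 0.12, or 0.19 without 17AAG tumour 1, camera adjusted p = 0.0461, adjusted p = 0.686 with an estimated correlation), a call lost without vehicle tumour 2 or 4 or 17AAG tumour 2 or 3 (adjusted p up to 0.262) and in 6 other fits. PGAM1 was their only member past the test over all genes. Within the list alone, 2 NRF2 genes were higher and 1 lower, 1 hypoxia gene was higher, and 0 passed in the other lists. The heat shock genes fixed in advance did not pass, with HSPA1A at -0.54 ± 0.35 (adjusted p = 0.445), DNAJB1 at 0.30 ± 0.19 (adjusted p = 0.444) and HSP90AA1 at -0.11 ± 0.15 (adjusted p = 0.777). TRIB3, a pseudokinase, was at 0.67 ± 0.23 (adjusted p = 0.135).

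The 17AAG calls rested on single tumours. The count was 1 gene without vehicle tumour 2, 18 without vehicle tumour 3 and 0 without vehicle tumour 4, 17AAG tumour 2 or 17AAG tumour 3. It was 396 without 17AAG tumour 1. Without vehicle tumour 3 the direction turned, with 13 higher and 5 lower. None of the 22 called genes taken by the fixed naming rule kept its call in each of these fits. With limma 0 genes passed when low genes were kept or the intensity trend was left out. The count was 84 without the 3 tumours over 40% mitochondrial reads and 1810 with array weights (831 higher, 979 lower). In the fit reported 2319 genes had an unadjusted p under 0.05, and voom called 187.

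The combination was compared with vehicle as the joint effect of both compounds, and 1862 genes passed, 884 higher and 978 lower. Inflammatory and alarmin genes were among the largest rises. S100A9 went from 237 ± 56.0 CPM (SD, n = 4) to 1210.4 ± 319 CPM (SD, n = 3), a log2 fold change of 2.34 ± 0.18 (adjusted p = 2.11e-07). Its partner S100A8 rose by 1.71 ± 0.22 (adjusted p = 2.89e-04) and the alarmin cytokine IL33 by 3.29 ± 0.52 (adjusted p = 9.08e-04). IL8 rose by 2.60 ± 0.43 (adjusted p = 0.00109), from 41.6 ± 21.7 to 245 ± 122 CPM (SD, n = 4 and n = 3). PTGS2, the inducible cyclooxygenase, rose by 2.38 ± 0.44 (adjusted p = 0.00225) and the cytokine IL24 by 2.18 ± 0.44 (adjusted p = 0.00399). The chemokine CXCL3 rose by 1.96 ± 0.32 (adjusted p = 0.00109) and IL1B by 1.70 ± 0.26 (adjusted p = 9.08e-04). The chitinase-like protein CHI3L2 (2.25 ± 0.41, adjusted p = 0.00207) and the scavenger receptor SCARA5 (2.13 ± 0.54, adjusted p = 0.0136) were also among the larger rises. SCARA5 lost its call without combination tumour 2 or 3 (adjusted p up to 0.0780).

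The NF-kB and inflammatory cytokine list rose (median 1.14, camera adjusted p = 5.89e-13, adjusted p = 0.184 with an estimated correlation). Of its 27 members, 15 rose, 0 fell and 12 did not pass, against 19 higher and 0 lower within the list alone. SOD2 rose by 1.62 ± 0.27 (adjusted p = 0.00140). Beside this list, 2 of the 5 tested macrophage and leukocyte markers rose, named here after their values were seen. CD68 went from 39.0 ± 10.2 to 81.4 ± 7.75 CPM (SD, n = 4 and n = 3), with adjusted p = 0.00154. CD14 went from 7.13 ± 0.659 to 16.4 ± 6.14 CPM (SD, n = 4 and n = 3), with adjusted p = 0.0210. CD14 lost its call without vehicle tumour 2 or combination tumour 2 or 3 (adjusted p up to 0.117). The leukocyte list did not pass (median 0.11, camera adjusted p = 0.0894, adjusted p = 0.259 with an estimated correlation), with 2 of its markers higher and 3 not passing. The squamous differentiation list rose (median 0.39, or 0.16 to 0.75 without vehicle tumour 1, 2 or 3 or combination tumour 2 or 3, camera adjusted p = 0.00360, adjusted p = 0.522 with an estimated correlation). Among 24 members, 5 rose, 1 fell and 18 did not pass, with 5 higher and 1 lower within the list alone. Besides S100A8 and S100A9 its examples are the serpins SERPINB4 (1.78 ± 0.26, adjusted p = 5.55e-04) and SERPINB3 (1.02 ± 0.20, adjusted p = 0.00309). These serpins share much of their sequence and are uncertain for that reason, as is CXCL3. Chosen after their values were seen, the ammonium transporter RHCG (1.38 ± 0.32, adjusted p = 0.00838) also rose, and the keratin KRT4 (-1.18 ± 0.39, adjusted p = 0.0491) was the fallen member. KRT4 lost its call without vehicle tumour 1, 2, 3 or 4 or combination tumour 2 or 3 (adjusted p up to 0.202).

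Genes that mark the epithelial state moved in both directions. The basal epithelial list rose (median 0.40, or 0.26 without combination tumour 1, camera adjusted p = 1.35e-05, adjusted p = 0.198 with an estimated correlation). Of its 26 members, 10 rose, 0 fell and 16 did not pass, against 11 higher and 1 lower within the list alone. The laminin subunits LAMB3 and LAMA3 rose, LAMB3 by 1.02 ± 0.17 (adjusted p = 0.00143) and LAMA3 by 1.00 ± 0.20 (adjusted p = 0.00403). ITGA6, a subunit of their integrin receptor, rose by 0.95 ± 0.17 (adjusted p = 0.00158). KRT5 (0.07 ± 0.21, adjusted p = 0.875) and KRT14 (0.29 ± 0.15, adjusted p = 0.211) did not pass. The luminal list did not pass (median 0.14, camera adjusted p = 0.622, adjusted p = 0.759 with an estimated correlation). Of its 22 members, 3 rose, 5 fell and 14 did not pass, against 5 higher and 6 lower within the list alone. GATA3 fell by 1.08 ± 0.20 (adjusted p = 0.00232), from 33.2 ± 5.13 to 15.9 ± 6.15 CPM (SD, n = 4 and n = 3). TSPAN1 rose by 1.18 ± 0.19 (adjusted p = 9.08e-04) and ALDH1A3, an aldehyde dehydrogenase of luminal progenitors, by 1.61 ± 0.33 (adjusted p = 0.00414). The other fallen members, named after their values were seen, were the stem cell antigen PROM1 (-1.22 ± 0.29, adjusted p = 0.00844), the adhesion protein EPCAM (-0.50 ± 0.14, adjusted p = 0.0192), and the receptors KIT (-1.26 ± 0.36, adjusted p = 0.0256) and ERBB3 (-0.54 ± 0.17, adjusted p = 0.0413). EPCAM lost its call without vehicle tumour 2 or combination tumour 2 or 3 (adjusted p up to 0.120), and KIT without vehicle tumour 1 or 2 or combination tumour 1, 2 or 3 (adjusted p up to 0.0913). ERBB3 lost its call without vehicle tumour 2 or 4 or combination tumour 2 or 3 (adjusted p up to 0.209). KRT8 (0.15 ± 0.15, adjusted p = 0.529) and KRT18 (0.16 ± 0.15, adjusted p = 0.514) did not pass. The mesenchymal list rose (median 0.27, or 0.51 without combination tumour 1, camera adjusted p = 0.00360, adjusted p = 0.198 with an estimated correlation). Of its 26 members, 7 rose, 0 fell and 19 did not pass, against 7 higher and 0 lower within the list alone. Its examples are the metalloproteinases MMP9 (1.72 ± 0.30, adjusted p = 0.00158) and MMP14 (0.95 ± 0.19, adjusted p = 0.00385). The matrix protein TGFBI (0.78 ± 0.14, adjusted p = 0.00179) also rose, whereas VIM was at 0.28 ± 0.17 (adjusted p = 0.289). The other genes reported here as having risen or fallen kept their calls without each tumour in turn.

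**Figure D2:**
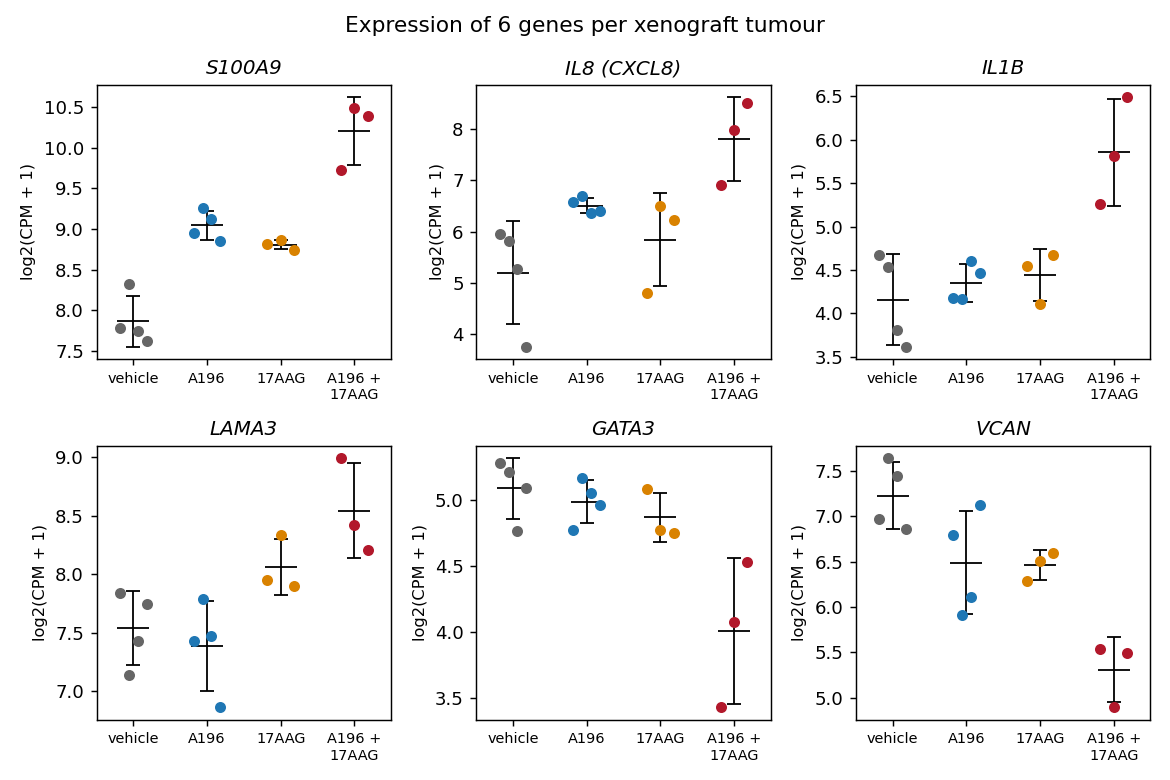
Expression of 6 genes as log2(CPM + 1) (vertical axes, which do not start at 0) in each tumour of the 4 groups, with 1 point per tumour and bars for the mean ± SD. The 3 combination tumours lie above all 4 vehicle tumours for S100A9, IL8, IL1B and LAMA3 and below them for GATA3 and VCAN.

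The unfolded protein response was measured with a list for each of its branches. The ATF6 target and ER chaperone list rose (median 0.33, camera adjusted p = 5.18e-05, adjusted p = 0.198 with an estimated correlation). Of its 24 members, 8 rose, 0 fell and 16 did not pass, against 9 higher and 0 lower within the list alone. The protein disulfide isomerases PDIA6 (0.53 ± 0.13, adjusted p = 0.0110) and PDIA4 (0.60 ± 0.17, adjusted p = 0.0238) rose. So did the secreted ER stress factor MANF (0.61 ± 0.16, adjusted p = 0.0148) and the chaperone HSPA5, or BiP (0.45 ± 0.13, adjusted p = 0.0308). The IRE1 and XBP1 target list rose (median 0.22, camera adjusted p = 0.00308, adjusted p = 0.198 with an estimated correlation). Over all genes 5 of its 26 members rose, 0 fell and 21 did not pass, and within the list alone 5 were higher and 0 lower. XBP1 itself rose (0.62 ± 0.13, adjusted p = 0.00514), as did EDEM1, of misfolded glycoprotein disposal (0.56 ± 0.13, adjusted p = 0.00858). The PERK and ATF4 target list did not pass (median -0.01, camera adjusted p = 0.589, adjusted p = 0.759 with an estimated correlation). Of its 28 members, 0 rose, 2 fell and 26 did not pass, against 0 higher and 2 lower within the list alone. The median of this list and its mean (0.09) differ in sign. The fallen pair was the serine synthesis enzyme PHGDH (-0.52 ± 0.12, adjusted p = 0.00839) and the stress protein NUPR1 (-0.73 ± 0.13, adjusted p = 0.00189), named after their values were seen. DDIT3, or CHOP (-0.24 ± 0.23, adjusted p = 0.523), ATF4 (-0.07 ± 0.12, adjusted p = 0.758) and TRIB3 (0.63 ± 0.23, adjusted p = 0.0759) did not pass. HERPUD1 was at -0.06 ± 0.21 (adjusted p = 0.894) and DNAJB9 at 0.54 ± 0.24 (adjusted p = 0.148). The ER-associated degradation list rose (median 0.21, or 0.13 without combination tumour 2, camera adjusted p = 0.0406, adjusted p = 0.301 with an estimated correlation). Of its 21 members, 3 rose, 1 fell and 17 did not pass, against 3 higher and 1 lower within the list alone. Examples are the segregase VCP (0.53 ± 0.12, adjusted p = 0.00635) and the lectin OS9 (0.46 ± 0.13, adjusted p = 0.0204). The N-glycosylation list rose (median 0.21, camera adjusted p = 0.00360, adjusted p = 0.301 with an estimated correlation). Over all genes 3 of its 30 members rose, 1 fell and 26 did not pass, and within the list alone 3 were higher and 1 lower. The sugar enzyme UAP1 rose (0.69 ± 0.15, adjusted p = 0.00451). The ER-associated degradation call was lost without vehicle tumour 3 or combination tumour 1 or 2 (adjusted p up to 0.0884) and in 8 other fits. HSPA5 and PDIA4 lost their calls without vehicle tumour 2 or 4 or combination tumour 2 or 3 (adjusted p up to 0.118), and MANF without vehicle tumour 2 or combination tumour 2 or 3 (adjusted p up to 0.0800). OS9 lost its call without vehicle tumour 4 or combination tumour 2 or 3 (adjusted p up to 0.0931), and PDIA6 and VCP without combination tumour 2 (adjusted p up to 0.0648).

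Chaperone genes outside the ER did not move as a list. The HSF1 target list did not pass (median 0.08, camera adjusted p = 0.272, adjusted p = 0.759 with an estimated correlation). Of its 30 members, 2 rose, 1 fell and 27 did not pass, against 2 higher and 1 lower within the list alone. The constitutive chaperone HSPA8 rose by 1.15 ± 0.29 (adjusted p = 0.0137). The small heat shock protein CRYAB fell by 0.76 ± 0.24 (adjusted p = 0.0402). HSPA1A was at -0.36 ± 0.35 (adjusted p = 0.525), HSP90AA1 at -0.24 ± 0.15 (adjusted p = 0.329) and DNAJB1 at 0.41 ± 0.19 (adjusted p = 0.160). The HSP90 client list rose (median 0.25, camera adjusted p = 0.00604, adjusted p = 0.198 with an estimated correlation). Among 20 members, 3 rose, 0 fell and 17 did not pass, with 5 higher and 0 lower within the list alone. EGFR (0.60 ± 0.13, adjusted p = 0.00623) and the kinase SRC (0.49 ± 0.14, adjusted p = 0.0228) rose. HSPA8 lost its call without vehicle tumour 2 or combination tumour 2 (adjusted p up to 0.0868), and CRYAB without vehicle tumour 1, 2, 3 or 4 or combination tumour 1, 2 or 3 (adjusted p up to 0.151). SRC lost its call without vehicle tumour 3 or 4 or combination tumour 1 or 3 (adjusted p up to 0.0885).

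Genes of the H4K20 methylation machinery were measured as the targets of A196 and their partners. The H4K20 methylation list did not pass (median -0.11, camera adjusted p = 0.487, adjusted p = 0.600 with an estimated correlation). Of its 19 members, 0 rose, 4 fell and 15 did not pass, against 0 higher and 4 lower within the list alone. The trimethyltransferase SUV420H2, a target of A196, fell by 0.86 ± 0.19 (adjusted p = 0.00713). The H4K20 demethylase RSBN1 fell by 0.60 ± 0.16 (adjusted p = 0.0141), and its relative RSBN1L fell by 0.88 ± 0.19 (adjusted p = 0.00497). The heterochromatin protein CBX5 fell by 0.41 ± 0.12 (adjusted p = 0.0348). SUV420H1 (0.15 ± 0.12, adjusted p = 0.415) and SETD8 (0.01 ± 0.13, adjusted p = 0.971) did not pass. The ZNF list fell (median -0.17, camera adjusted p = 9.03e-04, adjusted p = 0.184 with an estimated correlation). Over all genes 5 of its 420 members rose, 44 fell and 371 did not pass, and within the list alone 5 were higher and 36 lower. Examples are ZNF839 (-1.03 ± 0.17), ZNF91 (-1.01 ± 0.18), ZNF692 (-0.96 ± 0.17) and ZNF638 (-0.77 ± 0.12), with adjusted p between 9.08e-04 and 0.00179. The 5 risen, named after their values were seen, were ZNF575 (1.01 ± 0.27), ZNF622 (0.86 ± 0.22), ZNF771 (0.81 ± 0.17), ZNF185 (0.63 ± 0.18) and ZNF259 (0.51 ± 0.14). RSBN1 lost its call without vehicle tumour 2 or combination tumour 1 (adjusted p up to 0.0691), and CBX5 without vehicle tumour 1, 2 or 3 or combination tumour 1 or 3 (adjusted p up to 0.115). ZNF575 lost its call without vehicle tumour 2 or combination tumour 3 (adjusted p up to 0.0852), and ZNF622 without combination tumour 1 (adjusted p = 0.0995). ZNF185 lost its call without vehicle tumour 1 or 2 or combination tumour 1 or 2 (adjusted p up to 0.109), and ZNF259 without vehicle tumour 2, 3 or 4 or combination tumour 2 or 3 (adjusted p up to 0.0987).

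Metabolic and stress lists rose with the combination. The cholesterol synthesis list rose (median 0.45, camera adjusted p = 1.35e-05, adjusted p = 0.285 with an estimated correlation). Among 25 members, 7 rose, 0 fell and 18 did not pass, with 13 higher and 0 lower within the list alone. Lanosterol synthase LSS (0.74 ± 0.18, adjusted p = 0.00867) and SREBF2 (0.45 ± 0.11, adjusted p = 0.00930) rose. The hypoxia and glycolysis list rose (median 0.26, or 0.40 without vehicle tumour 3, camera adjusted p = 9.66e-05, adjusted p = 0.425 with an estimated correlation). Over all genes 8 of its 30 members rose, 0 fell and 22 did not pass, and within the list alone 10 were higher and 0 lower. It was led by the lipase inhibitor ANGPTL4 (1.75 ± 0.25, adjusted p = 5.33e-04) and the glucose transporter SLC2A1 (0.71 ± 0.13, adjusted p = 0.00229). The NRF2 target list rose (median 0.31, camera adjusted p = 9.66e-05, adjusted p = 0.184 with an estimated correlation). Among 23 members, 5 rose, 0 fell and 18 did not pass, with 7 higher and 0 lower within the list alone. Heme oxygenase HMOX1 (1.25 ± 0.28, adjusted p = 0.00678) and ferritin heavy chain FTH1 (1.11 ± 0.27, adjusted p = 0.0102) rose. The autophagy and lysosome list rose (median 0.27, camera adjusted p = 0.00308, adjusted p = 0.198 with an estimated correlation). Of its 28 members, 5 rose, 0 fell and 23 did not pass, against 10 higher and 0 lower within the list alone. Examples are the lysosomal protease CTSL (0.73 ± 0.13, adjusted p = 0.00212) and the proton pump subunit ATP6V0D1 (0.82 ± 0.17, adjusted p = 0.00451). The p53 target list rose (median 0.23, camera adjusted p = 0.0250, adjusted p = 0.285 with an estimated correlation). Among 24 members, 3 rose, 0 fell and 21 did not pass, with 3 higher and 0 lower within the list alone. The cyclin-dependent kinase inhibitor CDKN1A rose (1.36 ± 0.23, adjusted p = 0.00141). The antigen presentation list rose (median 0.26, camera adjusted p = 0.0159, adjusted p = 0.417 with an estimated correlation). Over all genes 2 of its 22 members rose, 0 fell and 20 did not pass, and within the list alone 2 were higher and 0 lower. HLA-E, whose reads can be shared with other HLA genes, rose (0.42 ± 0.12, adjusted p = 0.0222). The p53 call was lost without vehicle tumour 4 (adjusted p = 0.0678) and in 1 other fit. The antigen presentation call was lost without vehicle tumour 2 or combination tumour 3 (adjusted p up to 0.0927) and in 1 other fit. LSS and SREBF2 lost their calls without combination tumour 2 (adjusted p up to 0.0616), and FTH1 without combination tumour 2 or 3 (adjusted p up to 0.0555). HLA-E lost its call without vehicle tumour 1 or 4 or combination tumour 1 (adjusted p up to 0.0962).

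Lists of proliferation genes fell by camera with its preset correlation, while most members did not pass. The G2/M list fell (median -0.14, or -0.24 to -0.06 without vehicle tumour 2 or 4 or combination tumour 1, camera adjusted p = 0.0271, adjusted p = 0.702 with an estimated correlation). Over all genes 0 of its 30 members rose, 6 fell and 24 did not pass, and within the list alone 0 were higher and 6 lower. Topoisomerase TOP2A fell by 0.73 ± 0.12 (adjusted p = 0.00143), from 194 ± 26.1 to 117 ± 13.8 CPM (SD, n = 4 and n = 3). The kinetochore gene NDC80 fell by 0.73 ± 0.18 (adjusted p = 0.0119). The DNA replication list fell (median -0.22, or -0.13 without vehicle tumour 1, camera adjusted p = 0.0180, adjusted p = 0.600 with an estimated correlation). Of its 29 members, 0 rose, 5 fell and 24 did not pass, against 0 higher and 5 lower within the list alone. E2F1 (-0.68 ± 0.18, adjusted p = 0.0160) and the polymerase POLE (-0.52 ± 0.14, adjusted p = 0.0200) fell, as did ORC6 (-0.57 ± 0.19, adjusted p = 0.0496), named after its values were seen. The ribosomal protein list fell (median -0.12, or -0.20 without vehicle tumour 4, camera adjusted p = 0.0319, adjusted p = 0.759 with an estimated correlation). Among 82 members, 0 rose, 2 fell and 80 did not pass, with 0 higher and 0 lower within the list alone. RPL37 fell by 0.50 ± 0.14 (adjusted p = 0.0271). The G2/M call was lost without vehicle tumour 1 or 4 or combination tumour 1 or 3 (adjusted p up to 0.208) and in 1 other fit. The DNA replication call was lost without vehicle tumour 1 or combination tumour 3 (adjusted p up to 0.204). The ribosomal call was lost without vehicle tumour 2 or 3 or combination tumour 3 (adjusted p up to 0.426) and in 3 other fits. NDC80 lost its call without combination tumour 3 (adjusted p = 0.0656), and E2F1 without combination tumour 2 or 3 (adjusted p up to 0.0860). POLE lost its call without vehicle tumour 1 or 4 or combination tumour 2 or 3 (adjusted p up to 0.120), and RPL37 without vehicle tumour 2 or combination tumour 1, 2 or 3 (adjusted p up to 0.0806). ORC6 lost its call without vehicle tumour 1 or 4 or combination tumour 1, 2 or 3 (adjusted p up to 0.227).

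Among the largest falls was the matrix proteoglycan VCAN, which fell by 1.92 ± 0.24 (adjusted p = 1.89e-04), from 153 ± 39.6 to 39.4 ± 9.33 CPM (SD, n = 4 and n = 3). Others were the skeletal muscle troponin TNNI2 (-1.96 ± 0.44), the matrix protease ADAMTS5 (-1.83 ± 0.53), the lipocalin APOD (-1.75 ± 0.37), the collagen COL21A1 (-1.68 ± 0.35) and the transcription factor SOX6 (-1.65 ± 0.34). Their adjusted p ran from 1.89e-04 to 0.0269. ADAMTS5 lost its call without vehicle tumour 1 or combination tumour 1 or 2 (adjusted p up to 0.0912).

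**Figure D3:**
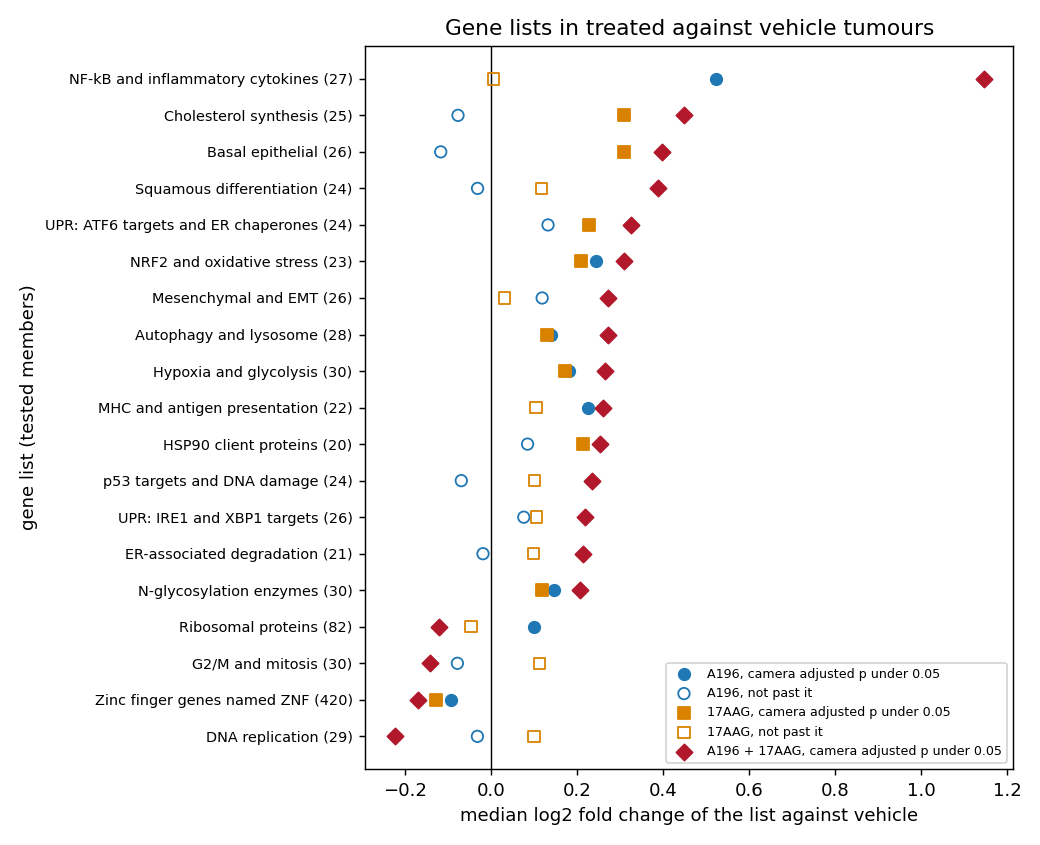
Median log2 fold change against vehicle (horizontal axis) of the 19 gene lists that passed camera for the combination (vertical axis, tested members in brackets), for A196 (circles), 17AAG (squares) and the combination (diamonds), filled where the list passed camera with its preset correlation. The NF-kB and inflammatory cytokine list lies at 0.52 with A196, 0.00 with 17AAG and 1.14 with the combination.

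At least 2-fold changes with the combination against vehicle numbered 151 rises and 228 falls. The count past the test was 878 without combination tumour 2 and 1081 without vehicle tumour 2, with 845 and 1044 of these among the 1862. More genes were higher than lower without combination tumour 2 (448 and 430), by voom (877 and 854) and with a GC and length trend removed (1065 and 924). Of the 96 called genes taken by the fixed naming rule, 53 kept their call without each tumour in turn. None of the 19 list calls held with an estimated correlation, where the lowest adjusted p was 0.184. For A196 and 17AAG against vehicle the lowest was 0.156 and 0.377. The rotation test fry, which asks whether a list's genes move 1 way on balance, called 17 lists for the combination, of which 13 were among the 19, and 0 for either single compound. It did not call the squamous, antigen presentation, G2/M, DNA replication, hypoxia and ribosomal lists (adjusted p from 0.0928 to 0.552). It called the H4K20, lactation, leukocyte and endothelial lists, which camera did not.

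Adding A196 to 17AAG was measured by the combination against 17AAG alone, where 7 genes rose and 0 fell. S100A9 rose by 1.40 ± 0.19 (adjusted p = 0.00207), from 447 ± 18.5 to 1210.4 ± 319 CPM (SD, n = 3 and n = 3). NAMPT, an enzyme of NAD synthesis, rose by 1.42 ± 0.18 (adjusted p = 0.00160). SOCS3, an inhibitor of cytokine signalling, rose by 1.71 ± 0.24 (adjusted p = 0.00312) and CXCL3 by 2.06 ± 0.34 (adjusted p = 0.0233). S100A8 (1.38 ± 0.24, adjusted p = 0.0282), SERPINB4 (1.55 ± 0.27, adjusted p = 0.0282) and the RNA-binding protein SAMD4A (1.72 ± 0.30, adjusted p = 0.0282) also rose. All 27 members of the NF-kB and inflammatory cytokine list were higher (median 1.11, camera adjusted p = 6.69e-31). Over all genes 1 rose, 0 fell and 26 did not pass, and 18 were higher within the list alone. This was the only list call in any comparison that held with an estimated correlation (adjusted p = 0.0240). IL1B was at 1.41 ± 0.28 (adjusted p = 0.0750) and CXCL1 at 1.11 ± 0.23 (adjusted p = 0.0753). SOCS3 lost its call without 17AAG tumour 3 or combination tumour 3 (adjusted p up to 0.0581), and CXCL3 without 17AAG tumour 1 or 3 or combination tumour 3 (adjusted p up to 0.165). SERPINB4 lost its call without 17AAG tumour 1 or 3 or combination tumour 2 or 3 (adjusted p up to 0.262), and S100A8 without 17AAG tumour 1, 2 or 3 or combination tumour 2 or 3 (adjusted p up to 0.165). SAMD4A lost its call without 17AAG tumour 1, 2 or 3 or combination tumour 1, 2 or 3 (adjusted p up to 0.165). NAMPT and S100A9 kept their calls without each tumour in turn.

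Proliferation lists were lower in the combination than with 17AAG alone. All 29 DNA replication genes were lower (median -0.26, camera adjusted p = 8.27e-10, adjusted p = 0.261 with an estimated correlation), as were 28 of 30 G2/M genes (median -0.30, camera adjusted p = 1.56e-10, adjusted p = 0.261 with an estimated correlation). Over all genes 0 of these members passed, and 2 and 0 were lower within the list alone. E2F1 was at -0.71 ± 0.19 (adjusted p = 0.222) and TOP2A at -0.45 ± 0.13 (adjusted p = 0.295). The mesenchymal (median 0.18, or 0.31 without 17AAG tumour 2, camera adjusted p = 6.90e-04), hypoxia and glycolysis (median 0.13, or 0.07 to 0.23 without 17AAG tumour 1 or 2, camera adjusted p = 3.69e-04) and NRF2 lists (median 0.17, or 0.09 without 17AAG tumour 1, camera adjusted p = 0.00279) rose, with adjusted p between 0.261 and 0.525 with an estimated correlation. In these 3 lists 0 members passed over all genes, and 2, 1 and 0 were higher within the list alone. The mesenchymal call was lost without combination tumour 2 (adjusted p = 0.0956). The hypoxia call was lost without 17AAG tumour 2 (adjusted p = 0.165). The squamous list rose (median 0.48, or -0.08 to 0.82 without 17AAG tumour 1 or 2, camera adjusted p = 6.90e-04, adjusted p = 0.523 with an estimated correlation). Among 24 members, 3 rose, 0 fell and 21 did not pass, with 5 higher and 1 lower within the list alone. Its median was negative without 17AAG tumour 2, and the call was lost without 17AAG tumour 2 or combination tumour 2 (adjusted p up to 0.550). The ATF6 target list rose (median 0.10, or 0.03 without 17AAG tumour 1, camera adjusted p = 0.0136, adjusted p = 0.476 with an estimated correlation), a call lost without 17AAG tumour 1 or combination tumour 2 (adjusted p up to 0.180) and in 2 other fits. The IRE1 target list rose (median 0.10, or 0.04 without 17AAG tumour 1, camera adjusted p = 0.0347, adjusted p = 0.377 with an estimated correlation), a call lost without 17AAG tumour 1 or 3 or combination tumour 1 or 2 (adjusted p up to 0.212) and in 2 other fits. Neither had a member past the test over all genes or within the list alone, with XBP1 at 0.44 ± 0.14 (adjusted p = 0.384) and HSPA5 at 0.20 ± 0.14 (adjusted p = 0.880). The ribosomal list fell (median -0.07, or -0.18 to 0.01 without 17AAG tumour 1, 2 or 3, camera adjusted p = 0.0487, adjusted p = 0.796 with an estimated correlation), with 0 of 82 members past either adjustment and a positive median without 17AAG tumour 1. The ribosomal call was lost without 17AAG tumour 1 or 3 or combination tumour 2 or 3 (adjusted p up to 0.583) and in 2 other fits.

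The 7 gene calls against 17AAG depended on single tumours and on the fit. The count was 3 without 17AAG tumour 1, 2 without 17AAG tumour 3 or combination tumour 3, and 25 without combination tumour 1. It was 22 with only these groups in the fit (21 higher, 1 lower) and 124 with array weights (73 higher, 51 lower). At an unadjusted p under 0.05 there were 924 genes (461 higher, 463 lower), and voom called 10.

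Adding 17AAG to A196 was measured by the combination against A196 alone, where 164 genes passed, 98 higher and 66 lower. The laminin subunit LAMA3 rose from 171 ± 42.9 to 382 ± 112 CPM (SD, n = 4 and n = 3), or by 1.15 ± 0.20 (adjusted p = 0.0106), and the integrin ITGA6 rose by 0.84 ± 0.17 (adjusted p = 0.0174). FERMT1, the epithelial kindlin that activates integrins, rose by 1.28 ± 0.22 (adjusted p = 0.0106). NT5E, the ectonucleotidase CD73, rose by 1.36 ± 0.22 (adjusted p = 0.00953) and S100A9 by 1.16 ± 0.18 (adjusted p = 0.00490). IL1B rose from 19.6 ± 3.15 to 60.4 ± 26.1 CPM (SD, n = 4 and n = 3, adjusted p = 0.0106). The adhesion receptor FLRT3 (1.24 ± 0.24, adjusted p = 0.0156) rose and the methyltransferase AS3MT (-1.51 ± 0.30, adjusted p = 0.0174) fell. FOLR1, a folate receptor, fell from 20.1 ± 3.94 to 7.17 ± 0.451 CPM (SD, n = 4 and n = 3, adjusted p = 0.0106). GATA3 fell by 0.98 ± 0.20 (adjusted p = 0.0231). LAMA3 and ITGA6 lost their calls without A196 tumour 4 or combination tumour 1 (adjusted p up to 0.0885), and IL1B and FOLR1 without A196 tumour 4 (adjusted p = 0.0553). FLRT3, AS3MT and GATA3 lost their calls without A196 tumour 4 or combination tumour 1 or 2 (adjusted p up to 0.113). FERMT1, NT5E and S100A9 kept their calls without each tumour in turn.

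Basal epithelial and cholesterol synthesis lists rose against A196. The basal epithelial list rose (median 0.53, camera adjusted p = 9.81e-15, adjusted p = 0.103 with an estimated correlation). Over all genes 6 of its 26 members rose, 0 fell and 20 did not pass, and within the list alone 17 were higher and 0 lower. The cholesterol synthesis list rose (median 0.45, camera adjusted p = 2.44e-10, adjusted p = 0.235 with an estimated correlation). Of its 25 members, 5 rose, 0 fell and 20 did not pass, against 13 higher and 0 lower within the list alone. The squalene epoxidase SQLE rose (0.80 ± 0.20, adjusted p = 0.0468), named after its values were seen. The squamous list rose (median 0.67, or 0.41 without A196 tumour 1, camera adjusted p = 5.23e-05, adjusted p = 0.443 with an estimated correlation). Over all genes 4 of its 24 members rose, 0 fell and 20 did not pass, and within the list alone 4 were higher and 1 lower. The NF-kB list rose (median 0.39, or 0.60 to 0.67 without A196 tumour 3 or combination tumour 1, camera adjusted p = 1.09e-06, adjusted p = 0.235 with an estimated correlation). Among 27 members, 2 rose, 0 fell and 25 did not pass, with 9 higher and 0 lower within the list alone. The risen pair was IL1A (1.03 ± 0.22, adjusted p = 0.0293) and IL1B. The mesenchymal list rose (median 0.19, or 0.12 to 0.29 without A196 tumour 3 or combination tumour 1, camera adjusted p = 0.00344, adjusted p = 0.235 with an estimated correlation). Over all genes 1 of its 26 members rose, 0 fell and 25 did not pass, and within the list alone 8 were higher and 0 lower. The risen member was TGFBI (0.94 ± 0.14, adjusted p = 0.00490). The ATF6 target (median 0.18, camera adjusted p = 9.24e-05), IRE1 target (median 0.15, camera adjusted p = 0.00637) and ER-associated degradation lists (median 0.15, or 0.08 without A196 tumour 3, camera adjusted p = 0.00637) rose, with adjusted p = 0.235 each with an estimated correlation. The last call was lost without the 3 tumours over 40% mitochondrial reads (adjusted p = 0.0588). In these 3 lists 0 members passed over all genes, and 4, 0 and 3 were higher within the list alone. SEL1L, a ubiquitin ligase subunit, was at 0.49 ± 0.13 (adjusted p = 0.0525). SQLE lost its call without A196 tumour 1 or 4 or combination tumour 1 or 2 (adjusted p up to 0.183), and IL1A without A196 tumour 1 or 4 or combination tumour 1, 2 or 3 (adjusted p up to 0.107). TGFBI kept its call without each tumour in turn.

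Other lists against A196 went both ways. The p53 target list rose (median 0.19, camera adjusted p = 0.00627, adjusted p = 0.235 with an estimated correlation). Of its 24 members, 1 rose, 0 fell and 23 did not pass, against 1 higher and 0 lower within the list alone. The risen member was CDKN1A (0.98 ± 0.23, adjusted p = 0.0385). The NRF2 target list rose (median 0.20, camera adjusted p = 0.0118, adjusted p = 0.235 with an estimated correlation). None of its 23 members passed over all genes, against 1 higher and 0 lower within the list alone. The hypoxia and glycolysis list rose (median 0.10, or 0.04 to 0.20 without A196 tumour 1, 3 or 4, camera adjusted p = 0.0222, adjusted p = 0.634 with an estimated correlation). Among 30 members, 1 rose, 0 fell and 29 did not pass, with 3 higher and 0 lower within the list alone. SLC2A1 was that member (0.59 ± 0.13, adjusted p = 0.0327). The HSP90 client list rose (median 0.10, or 0.05 without A196 tumour 2, camera adjusted p = 0.0224, adjusted p = 0.294 with an estimated correlation). None of its 20 members passed over all genes, against 3 higher and 0 lower within the list alone. The ribosomal protein list fell (median -0.22, or -0.14 without A196 tumour 3, camera adjusted p = 8.91e-09, adjusted p = 0.522 with an estimated correlation). Over all genes, or within the list alone, 0 of its 82 members passed. The DNA replication list fell (median -0.17, or -0.11 without A196 tumour 3 or combination tumour 3, camera adjusted p = 0.00963, adjusted p = 0.522 with an estimated correlation). None of its 29 members passed over all genes, against 0 higher and 1 lower within the list alone. The G2/M list fell (median -0.15, or -0.09 to -0.07 without A196 tumour 3 or combination tumour 1, camera adjusted p = 0.0240, adjusted p = 0.634 with an estimated correlation). Among 30 members, 0 rose, 1 fell and 29 did not pass, with 0 higher and 1 lower within the list alone. The fallen member was TOP2A (-0.54 ± 0.12, adjusted p = 0.0370). The ZNF list fell (median -0.10, camera adjusted p = 0.0361, adjusted p = 0.294 with an estimated correlation). Among 420 members, 0 rose, 1 fell and 419 did not pass, with 0 higher and 0 lower within the list alone. ZNF692 was that member (-0.70 ± 0.17, adjusted p = 0.0448). The type I interferon list fell (median -0.26, or -0.43 to -0.12 without A196 tumour 1 or combination tumour 1 or 2, camera adjusted p = 0.0493, adjusted p = 0.531 with an estimated correlation). Of its 27 members, 0 passed over all genes or within the list alone. The NRF2 call was lost without combination tumour 3 (adjusted p = 0.0628). The hypoxia call was lost without A196 tumour 1 or 4 or combination tumour 3 (adjusted p up to 0.173) and in 2 other fits. The HSP90 client call was lost without A196 tumour 2 or combination tumour 3 (adjusted p up to 0.0615) and in 1 other fit. The DNA replication call was lost without A196 tumour 3 or combination tumour 3 (adjusted p up to 0.187) and in 1 other fit. The G2/M call was lost without A196 tumour 3 or 4 or combination tumour 1 or 3 (adjusted p up to 0.318) and in 3 other fits. The ZNF call was lost without A196 tumour 1, 2 or 4 or combination tumour 1 or 2 (adjusted p up to 0.0960) and in 1 other fit. The interferon call was lost without A196 tumour 1 or 3 or combination tumour 1 or 3 (adjusted p up to 0.705) and in 10 other fits. CDKN1A and SLC2A1 lost their calls without A196 tumour 1 or 4 or combination tumour 1, 2 or 3 (adjusted p up to 0.125), and TOP2A without A196 tumour 3 or 4 or combination tumour 1 or 2 (adjusted p up to 0.147). ZNF692 lost its call without A196 tumour 2, 3 or 4 or combination tumour 1 or 2 (adjusted p up to 0.206).

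The 164 calls against A196 depended on single tumours and on the fit. The count was 8 without A196 tumour 4, 59 without combination tumour 1 and 40 without combination tumour 2. It was 52 when low genes were kept, 9 without the intensity trend and 108 after quantile normalization. It was 96 with only these groups in the fit, 283 with array weights and 248 after a GC and length trend was removed. More genes were lower than higher without combination tumour 3 (76 higher, 93 lower), without combination tumour 1 (26 higher, 33 lower) and without the intensity trend (3 higher, 6 lower).

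Whether A196 acted differently with and without 17AAG was tested by the interaction of the compounds. No gene passed with limma, 491 genes had an unadjusted p under 0.05, and voom called 0. The smallest adjusted p was 0.833, for the growth factor MDK (-1.09 ± 0.22). The other genes with the smallest p, given as values, were SERPINA5 (-1.29 ± 0.28), RPL39L (-1.07 ± 0.24), LRRC69 (1.69 ± 0.42), F3 (1.08 ± 0.28) and COL6A3 (0.92 ± 0.25). With camera 9 lists passed. The NF-kB and inflammatory cytokine (median 0.56, or 0.27 to 0.36 without vehicle tumour 2, A196 tumour 1, 17AAG tumour 1 or combination tumour 3, camera adjusted p = 3.35e-06), squamous (median 0.47, or 0.21 to 0.78 without A196 tumour 2, 17AAG tumour 1 or 2 or combination tumour 3, camera adjusted p = 0.00621), basal (median 0.21, or 0.11 to 0.13 without combination tumour 1 or 2, camera adjusted p = 0.00612) and cholesterol lists (median 0.13, or 0.06 to 0.22 without vehicle tumour 1, 3 or 4 or A196 tumour 3 or 4, camera adjusted p = 0.0478) were higher, with adjusted p between 0.643 and 0.701 with an estimated correlation. The NF-kB list had IL1B at 1.22 ± 0.37 and CXCL3 at 1.18 ± 0.45, both with adjusted p = 0.999. The G2/M (median -0.27, or -0.18 without combination tumour 1, camera adjusted p = 3.66e-06), DNA replication (median -0.28, camera adjusted p = 3.66e-06), type I interferon (median -0.31, or -0.12 without A196 tumour 1, camera adjusted p = 0.0229), oxidative phosphorylation (median -0.17, camera adjusted p = 4.71e-04) and ribosomal protein lists (median -0.18, or -0.29 to -0.07 without vehicle tumour 4, A196 tumour 3 or 17AAG tumour 1 or 2, camera adjusted p = 3.35e-06) were lower, with adjusted p between 0.643 and 0.696 with an estimated correlation. No member of any of these lists passed over all genes, and 1 ribosomal gene, RPL39L, was lower within the list alone. The basal call was lost without A196 tumour 4, 17AAG tumour 3 or combination tumour 1 (adjusted p up to 0.164). The squamous call was lost without vehicle tumour 2, A196 tumour 1 or 3, 17AAG tumour 2 or combination tumour 2 (adjusted p up to 0.665) and in 2 other fits. The cholesterol call was lost without vehicle tumour 1 or 4, A196 tumour 1, 2 or 4, 17AAG tumour 2 or 3 or combination tumour 1 or 2 (adjusted p up to 0.344) and in 4 other fits. The interferon call was lost without vehicle tumour 4, A196 tumour 1, 17AAG tumour 2 or 3 or combination tumour 1 (adjusted p up to 0.550) and in 3 other fits. The ribosomal call was lost without 17AAG tumour 1 (adjusted p = 0.0558) and in 1 other fit. Without each of the 14 tumours in turn 0 genes passed.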

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

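The tests of leukocyte markers, of GC content and length, and the fit without 3 tumours were chosen after the results were seen. Single tumours lay far from the other 3 of their group for 11 of 372 combinations of gene or list and group tested, where chance gives about 1 in 20, or 18.6. The gap to the nearest tumour, as a share of the group's range, was 0.881 for ALDH1A3 in vehicle tumour 1 and 0.953 in A196 tumour 3, both high. KCNJ15 was high in vehicle tumour 1 (0.833) and A196 tumour 1 (0.844). E2F1 was high in A196 tumour 1 (0.830), and UAP1 (0.861) and VIM (0.847) in vehicle tumour 3. A196 tumour 4 was low for FLRT3 (0.872) and high for LGALS9 (0.848). IFIT2 was low in vehicle tumour 4 (0.832) and TALDO1 in A196 tumour 2 (0.849).

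For 9 lists the change with A196 differed with and without 17AAG by the interaction test with the preset correlation. Their median differences were 0.56 for NF-kB and inflammatory cytokines, 0.47 for squamous, 0.21 for basal and 0.13 for cholesterol synthesis genes. They were -0.31 for interferon, -0.28 for DNA replication, -0.27 for G2/M, -0.18 for ribosomal protein and -0.17 for oxidative phosphorylation genes. With an estimated correlation none held (adjusted p between 0.643 and 0.701), and 7 of the 9 medians moved over 1.5 times without single tumours.

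The number of genes that changed with the combination against vehicle (1862) was weighed against the uneven mitochondrial share. With that share as a covariate 1704 genes passed, and without the 3 tumours over 40% it was 1503, which argues against either as the whole source. Of the 35 splits of the 7 tumours, 1 gave as many genes, the real split, and the highest of the others gave 215. This is the lowest share that 35 splits can give, so it argues against chance but does not exclude it. An effect of the compounds may account for the calls, as a hypothesis, and how mouse reads were treated stays open.

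The rise of inflammatory cytokine genes with the combination (median 1.14) could come from leukocytes in the tumour pieces. Of 28 leukocyte and neutrophil markers 21 are in the table and 7 reach 1 CPM in 3 tumours, and these went both ways, from -0.60 to 1.08, with CD68 (39.0 to 81.4 CPM) and CD14 (7.13 to 16.4 CPM) higher. The abundant leukocyte genes (4 in the table) summed to 23.9 CPM in combination tumours and 22.6 CPM in vehicle tumours, or 1.22% of the 1965 CPM that the cytokine genes gained, against leukocytes whose abundant transcripts were counted as their cytokines were. With the mitochondrial share as a covariate the median was 1.15. Leukocytes of the mouse host, whose reads were counted in a way that is not known, stay open, and a response of the tumour cells to both compounds remains as a hypothesis.

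The fall of ZNF genes with the combination (median -0.171, spread 0.0313) could follow GC content or transcript length. With that trend removed from each tumour the median was -0.143, and with the mitochondrial share as a covariate it was -0.168, so neither accounts for the whole fall. An effect of the compounds on these genes remains as a hypothesis, and the call with an estimated correlation did not hold (adjusted p = 0.184).

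Other splits were counted too. For A196 against vehicle 4 of 35 splits gave at least the real count of 1 gene, and the highest of the others gave 3, so chance was not excluded. It was 1 of 35 for 17AAG against vehicle (132 genes, highest other 19) and the combination against A196 (164, highest other 43). Each argues against chance without excluding it. The 10 splits for the combination against 17AAG are too few for a share under 0.05, with 7 genes in the real split and 0 as the highest other. For the interaction the real count was 0 with limma (491 genes at an unadjusted p under 0.05, 0 by voom), so that all 100 of 100 assignments reached it and the count says nothing about chance. Another assignment gave 318, where differences between the groups may fall in the interaction term, which was not tested.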

How the results depend on the processing

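Tests by voom, with the mitochondrial share as a covariate, without 3 tumours and with the GC and length trend removed were chosen after the data were seen. The number of genes past the test stayed within 1.5 times the reported one in all 6 contrasts with at least 5 CPM, pseudocounts of 0.25 and 5, upper quartile scaling, the mitochondrial covariate and voom (1, 187, 1731, 10, 223 and 0 genes for A196, 17AAG and the combination against vehicle, the combination against 17AAG and against A196, and the interaction). With limma the count for A196 (1) was 0 with low genes kept or without the intensity trend and 2 with array weights or only the groups compared. For 17AAG (132) it was 0 with low genes kept or without the trend, 1810 with array weights and 84 without the 3 tumours over 40% mitochondrial reads. For the combination against 17AAG (7) it was 124 with array weights and 22 with only the groups compared. Against A196 (164) it was 52 with low genes kept, 108 with quantile scaling, 9 without the trend, 283 with array weights, 96 with only the groups compared and 248 with the GC and length trend removed. The cause was not tested. That trend moved the share of higher calls for 17AAG from 25% to 37.8%, for the combination against A196 from 59.8% to 69.8% and against vehicle from 47.5% to 53.5%. The median of all genes lay furthest from 0 at -0.0365, for the combination against vehicle with upper quartile scaling.

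Leaving out each tumour in turn gave 0 to 2 genes for A196, 0 to 396 for 17AAG, 878 to 1645 for the combination against vehicle, 2 to 25 against 17AAG, 8 to 213 against A196 and 0 to 0 for the interaction. Each such fit has fewer tumours. With the tumour number as a block the counts were 4, 0, 1192, 17, 61 and 0 in that order. The numbers do not pair the tumours, since the deviations of 19 same-numbered pairs correlated between -0.272 and 0.176, and 5 of 14 tumours correlated best with their own number.

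Of the list calls (13, 9, 19, 10, 17 and 9 in the same order) 0, 0, 0, 1, 0 and 0 held with an estimated correlation, and fry called 0, 0, 17 (13 of them among the 19), 1, 1 and 0. Against 17AAG the ribosomal median turned to 0.0142 without 17AAG tumour 1 (adjusted p = 0.583) or without the 3 tumours over 40% mitochondrial reads (adjusted p = 0.523), and lay between -0.183 and 0.0142 with each tumour left out. The squamous median turned to -0.0830 without 17AAG tumour 2 (adjusted p = 0.550), in a range up to 0.818. For the genes followed one by one, 884 of 3958 alternative values of called genes lost the call, and of 10983 values in all 137 gained one and 0 turned in direction, and 62 of 189 calls held in every setting. For lists 304 of 1837 values of called lists lost the call, 3 of them turning in direction, and of 2178 in all 8 gained one, and without the 3 tumours over 40% mitochondrial reads 13 of 77 list calls were lost, 1 of them turning. Leaving out 1 tumour moved 8, 4, 8, 7, 10 and 7 of the list medians, in the same order, over 1.5 times. The planned count test (edgeR quasi-likelihood) was not run, and voom on the recovered reads was run in its place. At most 26.9% of simulated 1.5-fold changes were recovered.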

Other observations

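Genes named here other than CYC1, ATP5B, SDHB, UQCRB and TNNI2 were chosen after their values were seen. The remaining lists did not pass for the combination against vehicle, with adjusted p given from camera with the preset and then with an estimated correlation. Of 30 oxidative phosphorylation genes, 4 rose, CYC1 (0.46 ± 0.11), ATP5B (0.45 ± 0.12), UQCRC1 (0.37 ± 0.12) and SDHB (0.35 ± 0.10), and 2 fell, UQCRB (-0.46 ± 0.12) and COX6C (-0.38 ± 0.12), with adjusted p between 0.0102 and 0.0472. Adjusted over the list alone 7 were higher and 4 lower (median 0.06, adjusted p 0.589 and 0.759). The interferon genes OAS3 (0.67 ± 0.22, adjusted p = 0.0457) and IFITM1 (0.92 ± 0.31, adjusted p = 0.0489) rose, and adjusted over the list alone 0 of 27 passed (median 0.18, adjusted p 0.142 and 0.702). Of 26 junction genes the polarity gene LLGL2 (-0.70 ± 0.18, adjusted p = 0.0139) and EPCAM fell (median -0.00, adjusted p 0.723 and 0.824). Of 12 protocadherins PCDHGC3 rose (1.05 ± 0.28, adjusted p = 0.0181; median 0.16, adjusted p 0.375 and 0.702). None of 8 lactation genes (median 0.37, adjusted p 0.132 and 0.285), 17 histone genes (median 0.03, adjusted p 0.641 and 0.827) and 13 mitochondrially encoded genes passed (median -0.37, adjusted p 0.388 and 0.824).

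Markers of other cells were mixed. Of 6 endothelial markers ENG rose (0.72 ± 0.21, adjusted p = 0.0295; median 0.56, adjusted p 0.142 and 0.285), and of 16 fibroblast markers FAP rose (0.91 ± 0.26, adjusted p = 0.0247; median -0.12, adjusted p 0.622 and 0.759). None of 6 adipocyte markers passed (median -0.11, adjusted p 0.901 and 0.914), where the test pointed up. Too few members were tested as lists for muscle (TNNI2 fell, 1 of 4) and cancer-testis genes (SYCP3 fell, -1.03 ± 0.29, 1 of 2). CYC1 and TNNI2 kept their calls without each tumour in turn. Calls were lost for UQCRB without combination tumour 2 (adjusted p = 0.0725) and for LLGL2 also without vehicle tumour 2 (adjusted p up to 0.0701). PCDHGC3 and ENG lost theirs without vehicle tumour 2 or 4 or combination tumour 1 or 2 (up to 0.129), and OAS3 and IFITM1 without vehicle tumour 1, 2 or 4 or any combination tumour (up to 0.232). ATP5B and UQCRC1 lost theirs without vehicle tumour 2 or 4 or combination tumour 2 or 3, and UQCRC1 also without combination tumour 1 (up to 0.134). COX6C and SDHB lost theirs without vehicle tumour 1 or 2 or combination tumour 2 or 3, with vehicle tumour 4 for COX6C and 3 for SDHB (up to 0.155). FAP lost its call without vehicle tumour 3 or any combination tumour and SYCP3 without vehicle tumour 2 or 3 or combination tumour 3 (up to 0.104).

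The changes with A196 in the presence and absence of 17AAG, measured in groups that share no tumour, correlated across 13580 genes, which are not independent, at 0.336 (Pearson) and 0.286 (Spearman). All 7 genes that rose in its presence were higher in its absence.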
